A study of Mus musculus with 46 samples.

How the data were processed

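Poly(A) RNA was measured in the hippocampus of 46 mice of both sexes at 6 months of age. Per the labels, the animals were perfused with phosphate-buffered saline, RNA was purified with an NEB Monarch kit and libraries were made with a KAPA mRNA HyperPrep kit. The values deposited by the authors were whole-number counts per gene, 1 set per library. The submitters' processing notes name STAR, Salmon, DESeq2 and GRCm38 without roles or versions. Whether the counts are rounded estimates, which annotation release they used and which strand setting was applied is not given in the sources used here. Genes that overlap on opposite strands, such as antisense genes, and near-identical paralogs are therefore uncertain.

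Each of the 45706 gene identifiers was joined by its stable identifier to GENCODE release M 21 on GRCm38 for symbols and coordinates, and 45143 matched. Libraries held 10809187 to 16955596 counts. The numbers of the replicates follow the order of deposition and pair no animals. No labels of sequencing batch or date were given. Among 331 pairs of libraries of the same genotype, the lowest chi-squared per degree of freedom was 3.83, where 1 is expected for a library sequenced again, so each library was treated as a separate animal.

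Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on genotype (minimum count 10), which left 15309. Library sizes were scaled with TMM factors (0.961 to 1.0465), and a quasi-likelihood model with genotype and sex was fitted to the 46 libraries together. The 3 comparisons were Dp1Tyb with WT, Dp1Tyb;AppKO with WT and Dp1Tyb;AppKO with Dp1Tyb, each with two-sided tests and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the F statistic. Sex-dependent effects were tested as interactions. Levels are in CPM computed with TMM-scaled library sizes, given as mean ± SD over libraries.

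The genotype label of each library was checked against App, against the median level of 72 segment genes with a mean of at least 5 CPM and against sex chromosome genes. Libraries that went against their labels were kept and then left out in an added alternative.

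The 27 gene lists covered the duplicated segment without App (83 of 100 members measured), interferon response (51 of 60), interferon gamma response, interferon receptor signalling outside the segment, MHC class I, nucleic acid sensing, inflammatory cytokine and NF-kB, homeostatic and disease-associated microglia, astrocyte, myelinating oligodendrocyte, oligodendrocyte precursor, endothelial, mural and fibroblast, choroid plexus, hippocampal pyramidal, dentate granule and inhibitory neuron, thalamus and striatum, blood cells, synaptic, immediate early, App family and amyloid processing, oxidative phosphorylation, cytosolic ribosomal protein, stress and unfolded protein response, and clustered protocadherin beta. The lists, the comparisons, the first set of alternative settings and the rule for named genes were fixed before the data were examined. A list's score was its mean log2 CPM (prior count 2) per library. Genotype differences averaged over the sexes were tested by two-sided permutation within sex (100000 permutations, smallest p 1e-05, and 10000 for interactions). Benjamini-Hochberg adjustment was over the 81 tests of lists and comparisons. The 95% confidence intervals came from a linear model of the score on genotype and sex. They are not centred on the difference where the sexes are unbalanced, as in the comparisons with Dp1Tyb;AppKO. Each list was also tested with camera, at a preset correlation of 0.01 and at an estimated correlation, and with fry (limma 3.58.1). Fry asks whether the genes of a list move on balance in a single direction and does not compare the list with other genes. Counts given as adjusted over the list alone used Benjamini-Hochberg adjustment among its measured members.

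Genes were named by rule: App and the 4 receptor genes Ifnar1, Ifnar2, Ifngr2 and Il10rb; per comparison, the 8 genes of lowest p past the threshold in each direction outside the segment; the 4 highest and 4 lowest log2 fold changes in the segment among genes with a mean of at least 1 CPM; and up to 4 members of lowest p per list. Unnamed gene models were counted but not named. The level of 1 marker gene is not reported here. Genes named outside that rule are said to have been chosen after their values were seen.

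Alternatives were DESeq2 1.42.0, limma voom with quality weights, no filter, sex left out, only the compared genotypes, each sex alone, the animal number as covariate, 2 surrogate variables (sva 3.50.0), DESeq2 size factors, list members with a mean of at least 1 CPM, list medians and an estimated list correlation. Those added later were the fits without doubted libraries, without libraries low in hippocampal markers, without both, without each library in turn and with marker lists as covariates. For each comparison, 100 splits of its libraries into groups of the same sizes were drawn and tested. The overlap of the comparisons that share WT was set against 20 simulated runs without genotype effects.

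The gene test was tested on simulated data: negative binomial counts with the mean levels, dispersions and depths of these libraries, in which 200 genes were changed at 4 fold sizes. Recovery at 1.25-fold was 62.0%, 58.0% and 64.0% in the 3 comparisons, and at 1.5-fold it was 83.7%, 85.4% and 81.2%. Unchanged genes made up 6.15% to 6.67% of the calls. Genes were drawn independently, with no library of unusual composition or wrong label, so these rates hold for such data only. For the list test, with genes simulated as independent, 0 of 5 runs were called with no shift and 5 of 5 with a log2 shift of 0.1.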

Results

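Gene expression was measured by sequencing poly(A) RNA from the hippocampus of 46 mice aged 6 months. Dp1Tyb mice carry an extra copy of a segment of mouse chromosome 16 that corresponds to much of human chromosome 21, and App, the gene for the amyloid precursor protein, lies in that segment. The 16 wild-type (WT) libraries came from 8 males and 8 females, and so did the 16 Dp1Tyb libraries. The 14 libraries of Dp1Tyb mice that also carried an App knock-out allele (Dp1Tyb;AppKO) came from 8 males and 6 females. Total counts per library ran from 11084588 to 16236248 in WT, from 11300669 to 16259982 in Dp1Tyb and from 10809187 to 16955596 in Dp1Tyb;AppKO. Mitochondrial genes took between 6.1% and 11.85% of the counts of a library.

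App (ENSMUSG00000022892; GRCm38 chromosome 16, 84949685 to 85173766, minus strand), the gene whose copy number separates the genotypes with the duplication, was measured first, in each of the 46 libraries. Its mean level was 1529 ± 226 CPM (counts scaled to a common library size; SD, n = 16) in WT, 2215 ± 347 CPM (n = 16) in Dp1Tyb and 1536 ± 307 CPM (n = 14) in Dp1Tyb;AppKO. App was 1.45-fold higher in Dp1Tyb than in WT (log2 0.53, SE 0.086, adjusted p = 3.77e-05), with 16 of 16 libraries above the WT median, and it was 0.691-fold in Dp1Tyb;AppKO relative to Dp1Tyb (log2 -0.53, SE 0.089, adjusted p = 0.00481), with 14 of 14 libraries below the Dp1Tyb median. Between Dp1Tyb;AppKO and WT the log2 difference was -0.001 (SE 0.089, adjusted p = 0.997).

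App or the median level of 72 other genes of the segment went against the genotype label in 5 libraries. The library labelled WT replicate 5 had App at 2303 CPM and a segment level of 0.54 on the log2 scale against WT, while the library labelled Dp1Tyb replicate 4 had App at 1482 CPM and a segment level of 0.02. Both measures of those libraries lay in the range of the other genotype. In the libraries labelled Dp1Tyb replicate 1 and Dp1Tyb replicate 16, with segment levels of 0.58 and 0.57, App stood at 1584 and 1557 CPM, and in the library labelled Dp1Tyb;AppKO replicate 1, with a segment level of 0.55, it stood at 2282 CPM. Genes of the sex chromosomes went against the label in 0 libraries. Without these 5 libraries App was 1477 ± 95.6 CPM (n = 15) in WT, 2371 ± 100.3 CPM (n = 13) in Dp1Tyb and 1479 ± 229 CPM (n = 13) in Dp1Tyb;AppKO. The libraries then ran from 1284.5 to 1624 CPM in WT, from 2098 to 2468 CPM in Dp1Tyb and from 842.0 to 1660.2 CPM in Dp1Tyb;AppKO, with the lowest value in Dp1Tyb;AppKO replicate 11. All values below keep the labels and the 46 libraries as deposited, unless the 5 libraries are said to be left out.

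**Figure D1:**
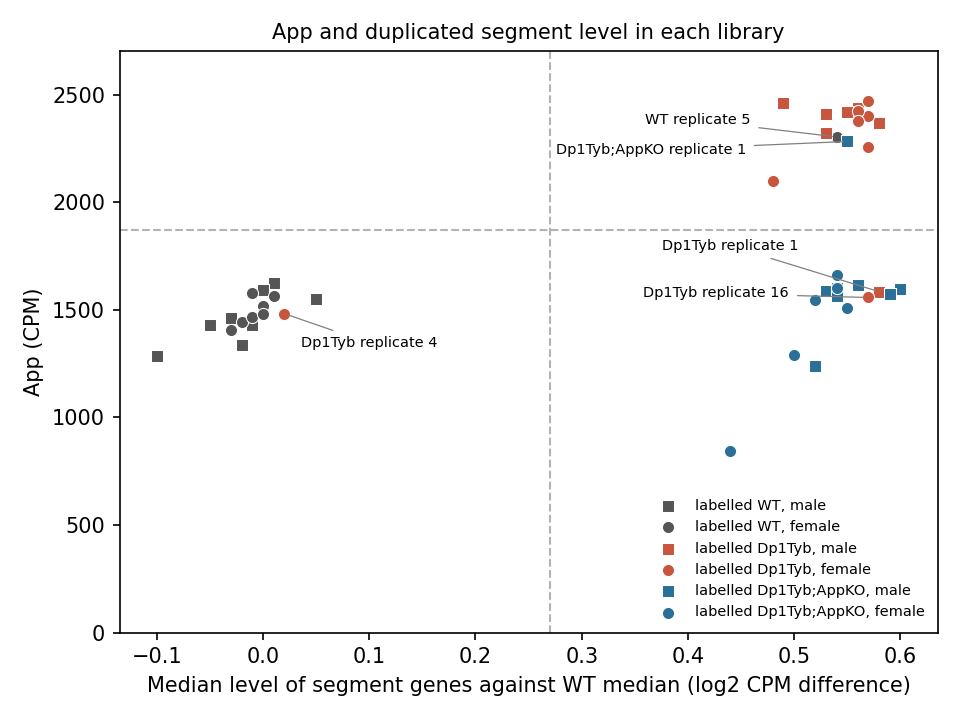
App level in CPM against the median log2 level of 72 other genes of the duplicated segment relative to WT, for each of the 46 libraries by genotype label. The libraries that went with their labels had segment levels of -0.10 to 0.05 in WT, 0.48 to 0.58 in Dp1Tyb and 0.44 to 0.60 in Dp1Tyb;AppKO, and 5 libraries lay outside their group in App, segment level or both.

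The comparison of Dp1Tyb with WT asked which genes change with the duplication. The listed genes of the duplicated segment (chromosome 16, 75540514 to 97962622) rose together. Among the 83 measured list genes other than App, 83 had a higher level in Dp1Tyb, and 70 of them were past the threshold. The 9 other tested genes of that interval had a median log2 change of 0.209, and 0 of them were called. The median over the 81 list genes with a mean of at least 1 CPM was 1.41-fold (log2 0.50, quartiles 0.44 and 0.56). It was 1.47-fold (log2 0.56) without the 5 libraries. Ripk4, a kinase of epithelial differentiation, had the highest ratio (log2 1.24, SE 0.243, adjusted p = 0.00103) at a level of 2.44 ± 0.939 CPM (n = 16) against 1.04 ± 0.631 CPM (n = 16). Bace2, a protease related to beta-secretase, rose by 0.89 on the log2 scale (adjusted p = 0.0272), and Rbm11, a splicing factor, by 0.71 (adjusted p = 8.32e-07). Clic6, a chloride channel protein expressed in choroid plexus, had a log2 difference of 0.80 with an SE of 0.507 (adjusted p = 0.464). At the low end stood Runx1 with 0.33 (adjusted p = 0.281), Pcp4 with 0.31 (adjusted p = 0.207) and Prdm15 with 0.23 (adjusted p = 0.0867), and Olig2, a transcription factor of the oligodendrocyte lineage, rose by 0.25 (adjusted p = 0.0393). The segment list as a whole was higher by 0.51 on the log2 scale (95% interval 0.40 to 0.63; permutation p = 1e-05, the smallest the permutations can give, adjusted p = 0.000405), with 81 genes higher when adjusted over the list alone.

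**Figure D2:**
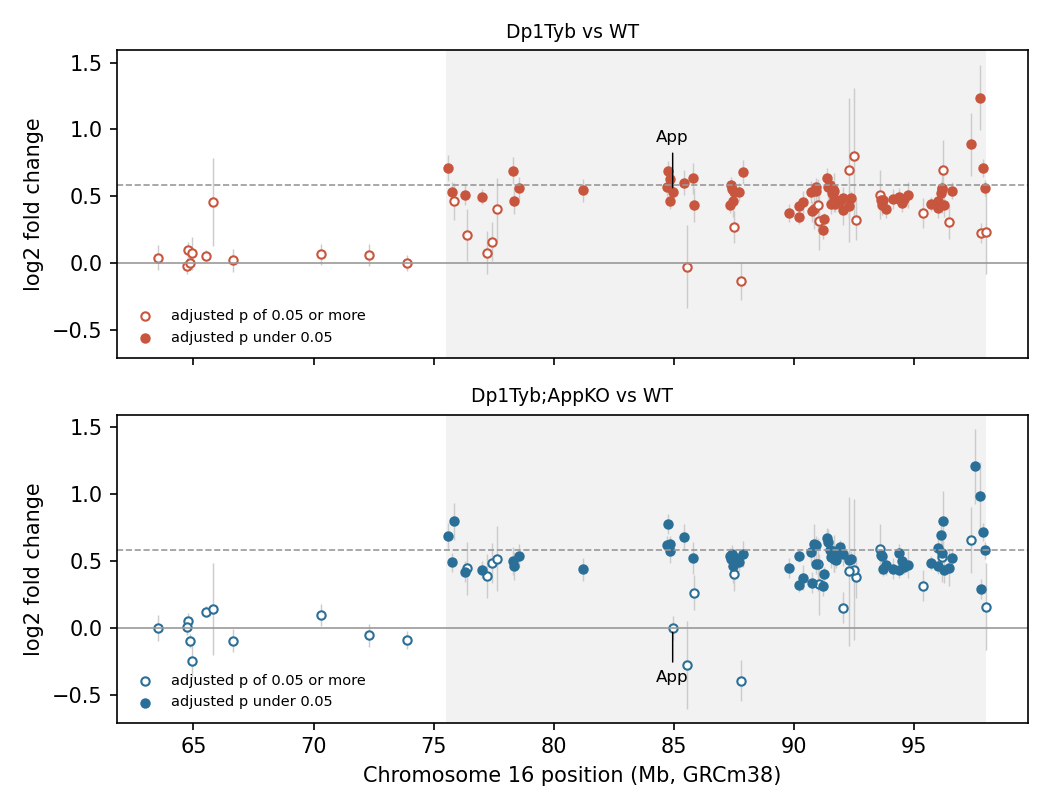
Log2 fold change against position on chromosome 16 (GRCm38), for the comparisons of Dp1Tyb with WT and Dp1Tyb;AppKO with WT. Genes with a mean of at least 1 CPM in the duplicated segment and beside it are shown. The medians of the listed segment genes with a mean of at least 1 CPM were 0.50 and 0.53, and App stands at 0.53 and -0.001.

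The genes of 4 interferon and cytokine receptor subunits lie in the segment and rose with it in Dp1Tyb. Ifnar1 (91485238 to 91507441), a subunit of the type I interferon receptor, rose 1.5-fold (log2 0.58, SE 0.057, adjusted p = 4.71e-10), from 41.1 ± 6.43 CPM in WT (n = 16) to 61.5 ± 7.38 CPM in Dp1Tyb (n = 16). Ifnar2 (91372783 to 91405589), its partner, rose by 0.63 on the log2 scale (adjusted p = 4.48e-08). Ifngr2 (91547072 to 91565623), a subunit of the interferon gamma receptor, rose by 0.44 (adjusted p = 0.000134), and Il10rb (91406164 to 91425834), a subunit shared by the receptors of interleukin 10 and interferon lambda, by 0.57 (adjusted p = 6.49e-05).

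Genes induced by type I interferon were higher in Dp1Tyb than in WT as a list. Of the 51 measured members, 49 had a higher level in Dp1Tyb, and 7 rose past the threshold over all genes (21 when adjusted over the list alone) while 0 fell. Trim25, a ubiquitin ligase that activates the RNA sensor RIG-I, rose by 0.47 on the log2 scale (SE 0.088, adjusted p = 0.000582), from 9.11 ± 1.51 to 12.6 ± 2.10 CPM (n = 16 each). Lgals3bp, a secreted glycoprotein, rose by 0.66 (adjusted p = 0.0166), Oasl2, a member of the oligoadenylate synthetase family, by 0.53 (adjusted p = 0.0239), and Ifi204, an interferon-inducible DNA sensor with close paralogs that leave its level uncertain, by 0.77 (adjusted p = 0.0241). The mean log2 level of the list was 1.92 ± 0.176 in WT (n = 16) and 2.19 ± 0.17 in Dp1Tyb (n = 16), a difference of 0.26 (95% interval 0.14 to 0.39; 1.20-fold), and 16 of 16 Dp1Tyb libraries stood above the WT median. The permutation test gave an adjusted p of 0.00437, camera with its preset correlation gave 1.46e-15 and fry gave 0.002, but the call was lost with camera at adjusted p = 0.0808 with an estimated correlation. The call was also lost with the median over members (0.237) and in each sex alone.

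**Figure D3:**
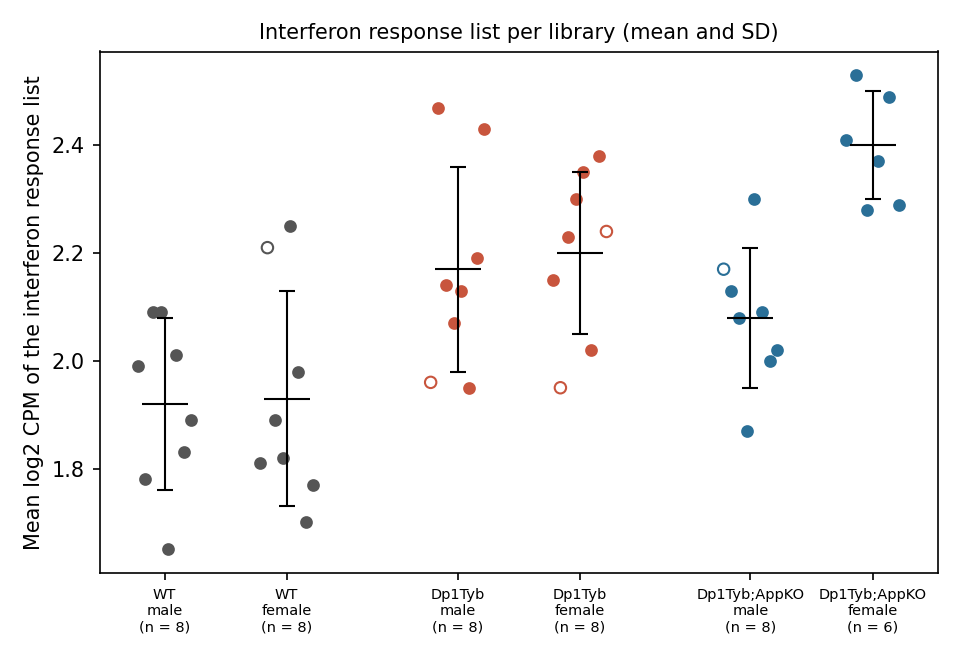
Mean log2 CPM of the 51 measured interferon response genes in each of the 46 libraries, by genotype and sex. The group means were 1.92 in WT, 2.19 in Dp1Tyb and 2.22 in Dp1Tyb;AppKO.

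Other immune lists gave smaller or less certain differences between Dp1Tyb and WT. In the MHC class I list, whose genes share reads among near-identical paralogs, H2-K1 rose by 0.28 (adjusted p = 0.0482), 2 members were higher when adjusted over the list alone, and the list differed by 0.26 (adjusted p = 0.144). The interferon gamma response list differed by 0.14 (adjusted p = 0.567). The list of interferon receptor signalling genes outside the segment differed by -0.001 (adjusted p = 0.981), nucleic acid sensing by 0.017 (adjusted p = 0.851), and inflammatory cytokine and NF-kB genes by 0.070 (adjusted p = 0.572). Within the homeostatic microglia list, Ctss, a lysosomal protease, rose by 0.17 (adjusted p = 0.0488), while the surface proteins Selplg and Tmem119 fell by 0.25 (adjusted p = 0.0106) and by 0.22 (adjusted p = 0.0457). That list differed by -0.047 (95% interval -0.12 to 0.023, adjusted p = 0.489) and the disease-associated microglia list by 0.052 (adjusted p = 0.651).

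Ribosomal protein genes were lower in Dp1Tyb than in WT by a small margin. The list of 36 cytosolic ribosomal protein genes differed by -0.13 on the log2 scale (95% interval -0.18 to -0.074; permutation test, adjusted p = 0.00162), with 0 of 36 members above the WT level and 16 of 16 Dp1Tyb libraries below the WT median. Rpl14 fell by 0.17 (adjusted p = 0.00825) and Rpl8 by 0.16 (adjusted p = 0.0236, and 0.0608 without the 5 libraries), and 31 members were lower when adjusted over the list alone; camera gave adjusted p = 0.633 with an estimated correlation. The oxidative phosphorylation list differed by -0.049 (95% interval -0.080 to -0.017; permutation test, adjusted p = 0.041, and 0.0688 without the 5 libraries), a call that ended when any of 24 single libraries was left out, and edgeR called 0 of its members over all genes or adjusted over the list alone; camera gave adjusted p = 0.874 with an estimated correlation.

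No other list passed the permutation test between Dp1Tyb and WT. Among glial and vascular lists, the astrocyte list differed by -0.011 (adjusted p = 0.904) while its member Fgfr3, a growth factor receptor, fell by 0.32 (adjusted p = 0.0245). The myelinating oligodendrocyte list differed by 0.11 (adjusted p = 0.481), with Mal, a myelin protein gene, higher by 0.41 (adjusted p = 0.0026). The oligodendrocyte precursor, endothelial, and mural and fibroblast lists differed by 0.005, 0.090 and 0.18 (adjusted p = 0.931, 0.36 and 0.36). Among neuronal lists, the hippocampal pyramidal, dentate granule, inhibitory and synaptic lists differed by -0.053, -0.22, 0.075 and -0.004 (adjusted p = 0.906, 0.36, 0.362 and 0.931). Dp1Tyb replicate 15 had the lowest pyramidal (5.1) and dentate granule (3.64) scores of the Dp1Tyb libraries. The SDs of these lists were 0.349 and 0.55 in Dp1Tyb against 0.153 and 0.188 in WT. Without the 5 libraries the inhibitory list differed by 0.12 (permutation test, adjusted p = 0.0547), and camera with an estimated correlation gave adjusted p = 0.258. The permutation test passed when the 4 libraries low in pyramidal or dentate markers were left out as well (0.12, adjusted p = 0.0359). Marcksl1, a dentate granule list member, fell by 0.33 (adjusted p = 0.000709). Btg2 of the immediate early list fell by 0.41 (adjusted p = 0.025), and that list differed by -0.23 (adjusted p = 0.36). Clu, a chaperone gene in the list of App family and amyloid processing genes, fell by 0.12 (adjusted p = 0.0467), and that list differed by 0.001 (adjusted p = 0.973). The integrated stress and unfolded protein response list differed by -0.012 (adjusted p = 0.851), clustered protocadherin beta genes by 0.026 (adjusted p = 0.812), markers of neighbouring thalamus and striatum by -0.011 (adjusted p = 0.931), choroid plexus by 0.21 (adjusted p = 0.906) and blood cells by 0.19 (adjusted p = 0.904).

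Outside the segment interval, 152 genes were higher and 162 lower in Dp1Tyb than in WT among 15216 tested. The median absolute log2 change of the called genes was 0.241. The agouti gene a (ENSMUSG00000027596, chromosome 2, 154791402 to 155051012, plus strand), which encodes a pigment signalling protein of the skin, had the highest ratio of those named (log2 4.42, SE 0.455, adjusted p = 2.03e-09) at a level of 1.12 ± 0.637 CPM (n = 16) against 0.0499 ± 0.119 CPM (n = 16). Without the 5 libraries its log2 change was 5.18. Vwf, the gene for von Willebrand factor of endothelial cells, rose by 0.69 (adjusted p = 2.37e-05), from 20.8 ± 3.80 to 33.7 ± 5.84 CPM. Slc5a5, a sodium iodide transporter, rose by 0.65 (adjusted p = 3.99e-06). Smaller rises were measured for Hrsp12 (0.48), Ddo (0.46), an oxidase of D-aspartate, the antisense gene Dlx6os1 (0.44), Qpct (0.39) and Coasy (0.26), with adjusted p between 4.06e-05 and 9.55e-05. Tnc, the extracellular matrix protein tenascin C, fell by 0.93 (SE 0.12, adjusted p = 3.4e-07), from 7.62 ± 2.55 to 4.02 ± 0.881 CPM. Cbs, a cystathionine synthase of sulfur amino acid metabolism, fell by 0.71 (SE 0.089, adjusted p = 1.74e-07), from 22.1 ± 2.998 to 13.5 ± 2.77 CPM. Mfge8, a secreted protein that bridges dying cells to phagocytes, fell by 0.47 (adjusted p = 1.14e-06), from 129.8 ± 12.7 to 94.1 ± 16.2 CPM. Agt, the gene for angiotensinogen, fell by 0.63 (adjusted p = 0.000102), and Pnrc1 fell by 0.40 (SE 0.046, adjusted p = 2.37e-08). Falls of 0.35 to 0.28 were measured for Mxd4, St3gal1 and Adgrg1, with adjusted p between 2.29e-06 and 7.5e-05.

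In total, edgeR called 385 genes between Dp1Tyb and WT, 223 higher and 162 lower. This number was 443 without the 5 libraries and 1122 without 4 libraries whose pyramidal or dentate granule markers stood far below those of the other libraries.

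The comparison of Dp1Tyb;AppKO with WT asked what the duplication changes when App is back at the usual copy number. The listed segment genes rose here too, with 83 of 83 other than App at a higher level and 72 past the threshold. The 9 other tested genes of the interval had a median log2 change of 0.387, and 0 of them were called. The median over the 81 list genes with a mean of at least 1 CPM was 1.44-fold (log2 0.53, quartiles 0.45 and 0.58). Ripk4 rose by 0.99 (adjusted p = 0.0146), Samsn1, an adaptor protein of lymphoid cells, by 0.80 (adjusted p = 0.00013), Sh3bgr by 0.80 (adjusted p = 0.0336) and Jam2, a junction protein of vessels, by 0.78 (adjusted p = 2.2e-10). At the low end, Olig2 rose by 0.31 (adjusted p = 0.00465) and Prdm15 by 0.29 (adjusted p = 0.0186), while Adamts5 differed by 0.27 (adjusted p = 0.326) and Slc5a3 by 0.15 (adjusted p = 0.591). The segment list was higher by 0.52 (95% interval 0.42 to 0.63; permutation test, adjusted p = 0.000405), with 78 genes higher when adjusted over the list alone. Ifnar1 rose by 0.59 (SE 0.058, adjusted p = 6.39e-10) to 61.5 ± 3.14 CPM (n = 14), Ifnar2 by 0.67 (adjusted p = 1.84e-08), Ifngr2 by 0.53 (adjusted p = 6.94e-06) and Il10rb by 0.64 (adjusted p = 9.42e-06).

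The interferon response list was higher in Dp1Tyb;AppKO than in WT as well. Of its 51 measured members, 50 had a higher level, 11 rose past the threshold over all genes (20 when adjusted over the list alone) and 0 fell. Ifit3b, an interferon-induced gene that shares reads with its near-identical neighbour Ifit3 and is therefore uncertain, rose by 0.72 (adjusted p = 0.000255), Ifi204 by 0.97 (adjusted p = 0.0019), Dhx58, a regulator of RNA sensing, by 0.78 (adjusted p = 0.00939) and Xaf1, a gene of apoptosis, by 0.49 (adjusted p = 0.00967). The list mean was 2.22 ± 0.198 (n = 14), a difference of 0.32 from WT with the sexes weighted equally. The 95% interval of the model with genotype and sex was 0.17 to 0.44, and 13 of 14 libraries stood above the WT median. The permutation test gave an adjusted p of 0.00162, camera with its preset correlation gave 4.55e-16 and fry gave 0.0017, while camera gave adjusted p = 0.0808 with an estimated correlation. Of the 13 members past the threshold in either comparison with WT, 5 were past it in both: Ifi204, Ifit3b, Oasl2, Trim25 and Xaf1.

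Other immune genes rose individually in Dp1Tyb;AppKO against WT. B2m, the light chain of MHC class I, rose by 0.34 (adjusted p = 0.00175) and H2-K1 by 0.37 (adjusted p = 0.00431), 3 members of that list were higher when adjusted over the list alone, and the list differed by 0.29 (95% interval 0.086 to 0.49, adjusted p = 0.0631). Ctss rose by 0.27 (adjusted p = 0.000503), and the homeostatic microglia list differed by 0.048 (95% interval -0.058 to 0.14, adjusted p = 0.652). The interferon gamma response list differed by 0.21 (adjusted p = 0.402), nucleic acid sensing by 0.052 (adjusted p = 0.414), and disease-associated microglia by 0.085 (adjusted p = 0.36). Interferon receptor signalling outside the segment and inflammatory cytokine and NF-kB genes differed by 0.011 and 0.044 (adjusted p = 0.904 and 0.69).

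Glial and vascular markers changed one by one in Dp1Tyb;AppKO against WT, while no list of cell type or tissue markers passed its permutation test. The astrocyte genes Ntsr2 and S100b rose by 0.27 (adjusted p = 0.00028) and 0.29 (adjusted p = 0.002), and Fgfr3 fell by 0.36 (adjusted p = 0.01). The myelin genes Mal, Mobp and Mog rose by 0.52 (adjusted p = 9.28e-05), 0.38 (adjusted p = 0.00452) and 0.30 (adjusted p = 0.0234), and the oligodendrocyte precursor list member Bcas1 by 0.33 (adjusted p = 0.00472). The endothelial genes Ly6a and Ly6c1, which belong to a family of close paralogs, rose by 0.38 (adjusted p = 0.0129) and 0.32 (adjusted p = 0.0428, and 0.0866 for Ly6c1 without the 5 libraries), and the dentate granule list member Marcksl1 fell by 0.26 (adjusted p = 0.0131). The differences of these lists were 0.045 for astrocytes, 0.16 for myelinating oligodendrocytes, -0.013 for precursors, 0.081 for endothelium and -0.10 for dentate granule neurons (adjusted p = 0.651, 0.356, 0.906, 0.527 and 0.83). Dp1Tyb;AppKO replicate 12 had the lowest dentate granule score of its genotype (4.43), and the SD was 0.432 against 0.188 in WT. The remaining cell type and tissue lists, which were pyramidal, inhibitory, mural and fibroblast, choroid plexus, thalamus and striatum, and blood, had adjusted p between 0.613 and 0.917. Ribosomal protein genes differed by 0.012 (permutation test, adjusted p = 0.931) and oxidative phosphorylation by 0.030 (adjusted p = 0.652). The SD of the ribosomal list was 0.212 against 0.077 in WT, with 5 of 14 libraries above the WT median. Dp1Tyb;AppKO replicate 11 had the highest score of both lists (7.855 for the ribosomal list), and the differences from WT without it are not given here. Immediate early genes differed by -0.20 (adjusted p = 0.459), synaptic genes by -0.064 (adjusted p = 0.467) and App family genes by -0.048 (adjusted p = 0.176). The stress response list differed by -0.012 (adjusted p = 0.851) and protocadherin beta genes by -0.075 (adjusted p = 0.567).

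Outside the segment interval, 269 genes were higher and 154 lower in Dp1Tyb;AppKO than in WT. The agouti gene again had the highest ratio of those named (log2 4.60, adjusted p = 6.37e-10, at 1.27 ± 0.377 CPM, n = 14). The largest fold change among genes called outside the region was 24.3 with all libraries and 39.6 without the 5 libraries. The metallothionein genes Mt2 and Mt1, which bind metal ions, rose by 0.63 (adjusted p = 1.73e-07) and 0.40 (adjusted p = 6.88e-07), with Mt2 at 62.1 ± 13.3 CPM against 40.1 ± 4.803 CPM. Sp7, a transcription factor of bone formation, rose by 0.94 (adjusted p = 2.73e-06), Hrsp12 by 0.69 (adjusted p = 1.99e-08), Slc5a5 by 0.64 (adjusted p = 9.26e-06), Cst3, the gene for cystatin C, by 0.34 (adjusted p = 9.06e-06) and Abhd4 by 0.31 (adjusted p = 4.54e-06). Tnc fell by 1.05 (adjusted p = 5.52e-08) to 3.66 ± 0.625 CPM, Cbs by 0.77 (adjusted p = 6.44e-08) to 12.95 ± 2.659 CPM, and Mfge8 by 0.58 (adjusted p = 1.85e-08) to 86.6 ± 11.6 CPM. St3gal1 fell by 0.42, Adgrg1, Pnrc1 and Pik3r3 each by 0.33, and Irf2bpl by 0.20, with adjusted p between 2.01e-06 and 2.34e-05. In total, 495 genes were called, 341 higher and 154 lower, and the number was 761 without the 4 libraries low in pyramidal or dentate markers.

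The direct comparison of Dp1Tyb;AppKO with Dp1Tyb asked what the third App copy adds. App itself was the only gene past the threshold with edgeR among 15309 tested, with 1650 genes at an unadjusted p under 0.05. The limma voom test also called 1 gene, App (log2 -0.46, adjusted p = 0.0289), with 1080 at an unadjusted p under 0.05. DESeq2 called 3, which were App, Lnp (log2 -0.23, adjusted p = 0.0399) and Sec14l2 (log2 0.20, adjusted p = 0.0399), with 1660 unadjusted. The latter pair was named after the values were seen. With the animal number as covariate, edgeR and limma voom called 0 genes and DESeq2 called App alone. The other segment genes differed by a median of 0.015 (quartiles -0.038 and 0.072), edgeR, DESeq2 and limma voom each called 0 of them, and the list differed by 0.010 (95% interval -0.082 to 0.097, adjusted p = 0.931). At the ends of their range stood Samsn1 with 0.34 (adjusted p = 0.381), Slc5a3 with -0.24 (adjusted p = 0.441) and Clic6 with -0.37 (adjusted p = 0.827). Ifnar1, Ifnar2, Ifngr2 and Il10rb differed by 0.002, 0.041, 0.088 and 0.072 (adjusted p = 0.993, 0.878, 0.701 and 0.813).

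The interferon response list differed by 0.053 between Dp1Tyb;AppKO and Dp1Tyb (95% interval -0.083 to 0.17; permutation test, p = 0.387, adjusted p = 0.713), with 29 of 51 members at a higher level in Dp1Tyb;AppKO. Over all genes and adjusted over the list alone, edgeR called 0 of its members. Without the 5 libraries the difference was 0.012 (95% interval -0.13 to 0.13). Against the excess of 0.26 of Dp1Tyb over WT, the interval leaves out a fall of the list to the WT level and leaves in a fall of 0.083. The MHC class I list differed by 0.031 (adjusted p = 0.904), the interferon gamma response by 0.061 (adjusted p = 0.812), homeostatic microglia by 0.095 (95% interval 0.019 to 0.17, adjusted p = 0.112) and disease-associated microglia by 0.033 (adjusted p = 0.837).

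Ribosomal protein and oxidative phosphorylation genes passed the permutation test as lists between Dp1Tyb;AppKO and Dp1Tyb, but neither call held without the 5 libraries against their labels or without the 4 low in pyramidal or dentate markers. The ribosomal list differed by 0.14 (95% interval 0.029 to 0.24; permutation test, adjusted p = 0.025), with 34 members higher when adjusted over the list alone, and the oxidative phosphorylation list by 0.079 (95% interval 0.022 to 0.13; adjusted p = 0.025), with 6 members. Over all genes edgeR called 0 members of either list, and camera gave adjusted p = 0.424 and adjusted p = 0.355 with an estimated correlation. The spread was wider in Dp1Tyb;AppKO, with SDs of 0.212 against 0.073 for the ribosomal list and 0.097 against 0.039 for oxidative phosphorylation. The library Dp1Tyb;AppKO replicate 11, which was low in pyramidal markers and had the highest mitochondrial share of the 46 libraries (11.85%), also had the highest score of both lists, and without it the differences were 0.079 and 0.049 (adjusted p = 0.11 for each). Without the 4 libraries low in pyramidal or dentate markers they were 0.078 (adjusted p = 0.091) and 0.040 (adjusted p = 0.177), and without the 5 libraries against their labels 0.14 (adjusted p = 0.0738) and 0.073 (adjusted p = 0.0953). Apart from homeostatic microglia with 0.112, each list that did not pass had an adjusted p of at least 0.18 in this comparison. The App family and amyloid processing list, which does not hold App, differed by -0.049 (adjusted p = 0.18).

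The changes outside the segment were compared between Dp1Tyb and Dp1Tyb;AppKO, each against WT. Among 15216 genes, 94 were higher in both comparisons where n1×n2/N gave 2.7 by chance, 67 were lower in both where chance gave 1.6, and 0 were called in opposite directions. Tnc, Cbs, Mfge8, Pnrc1, Hrsp12 and Slc5a5 were among the genes called the same way in both. The correlation of log2 changes across genes, which are not independent replicates, was 0.638 with a covariance of 0.0173. Because both comparisons share the WT libraries, simulated data with no genotype effect also gave a correlation of 0.476 and a covariance of 0.00949. The measured covariance exceeded the simulated one by 0.00781, and the simulated runs had 0 genes called in both. The numbers by chance of 2.7 and 1.6 take the comparisons as independent. A single shared WT library can still put genes in both counts. Car8 and Fat2 were called lower in both comparisons, and in neither without WT replicate 7. With the WT libraries split into separate controls, 13 genes were higher in both (chance 0.3) and 11 lower in both (chance 0.1), at a correlation of 0.278 and a covariance of 0.00947. Of the 576 genes called in either comparison, edgeR called 0 in the direct comparison and 157 had an unadjusted p under 0.05 there, 112 of them higher in Dp1Tyb;AppKO. Over all 15216 genes outside the segment interval 1642 had such a p, and the 576 were chosen by comparisons that use the same libraries.

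Differences between the sexes in the genotype effects were tested by interaction. For individual genes edgeR called 0 in each of the 3 comparisons, with 662, 1200 and 388 genes at an unadjusted p under 0.05 where chance gives 765. DESeq2 also called 0, with 652, 1213 and 399 unadjusted, and limma voom 0, with 961, 1678 and 1108. The interferon response list averaged 1.92 in WT males, 1.93 in WT females, 2.17 in Dp1Tyb males, 2.20 in Dp1Tyb females, 2.08 in Dp1Tyb;AppKO males and 2.4 in Dp1Tyb;AppKO females. The difference of Dp1Tyb;AppKO from WT was 0.17 in males and 0.47 in females (permutation test of the interaction, p = 0.014, adjusted p = 0.296). From Dp1Tyb it was -0.087 in males and 0.19 in females (permutation test of the interaction, p = 0.0132, adjusted p = 0.296). The ribosomal protein list differed between Dp1Tyb and WT by -0.19 in males and -0.067 in females (permutation test of the interaction, p = 0.0171, adjusted p = 0.296). Homeostatic microglia differed by -0.12 in males and 0.028 in females between Dp1Tyb and WT (permutation test of the interaction, p = 0.0237, adjusted p = 0.296), and by -0.070 and 0.17 between Dp1Tyb;AppKO and WT (p = 0.0097, adjusted p = 0.296). Of the 81 interaction tests of lists, 9 had an unadjusted p under 0.05, where chance gives 4, and 0 passed adjustment. The list interactions are given with the 46 libraries only. The libraries labelled WT replicate 5 and Dp1Tyb replicate 4, whose segment levels went against their labels, are both female. The segment list differed between Dp1Tyb and WT by 0.60 in males and 0.43 in females. The permutation test of that interaction gave p = 0.135 (adjusted p = 0.643).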

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

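The fits without libraries and the fits with a marker list as covariate were chosen after seeing the data, and the other alternatives were planned. Over 20 results and 225 alternatives, 168 kept their direction and their side of the threshold or stayed within 1.5 times the reported count, 22 counts moved further, 23 values lost significance, 1 gained it and 11 changed sign. The causes were not tested. Each sex alone leaves fewer libraries, which does not by itself account for females. The libraries whose segment levels went against their labels, WT replicate 5 and Dp1Tyb replicate 4, are both female. In females, Dp1Tyb against WT gained genes when the doubted libraries were left out as well.

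For Dp1Tyb against WT, the 385 genes became 1145 with limma voom, 633 with 2 surrogate variables, 1122 without the 4 libraries low in hippocampal markers and 1241 without those and the 5 doubted libraries together. Females alone gave 0 genes with edgeR (878 at an unadjusted p under 0.05, 58 called by DESeq2, 51 by limma voom), 0 segment genes and App at 0.42 (adjusted p = 0.508, against a range of 2.13e-18 to 0.508 over its alternatives), and without the doubted libraries they gave 64 genes and 46 segment genes. For Dp1Tyb;AppKO against WT, the 495 genes became 916 with 2 surrogate variables, 761 without the low-marker libraries, 805 without both kinds, 273 in males, 66 in females, and 210 and 113 in males and females without the doubted libraries. The segment genes there numbered 22 in females and 44 in females without the doubted libraries. The direct comparison gave 3 genes with DESeq2, 2 without the low-marker libraries, and with edgeR 0 in males, in females and with the animal number as covariate (955, 1040 and 1295 at an unadjusted p under 0.05; 4, 0 and 1 called by DESeq2; 0, 0 and 0 by limma voom).

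App changed sign between Dp1Tyb;AppKO and WT, from -0.001 to 3.2e-05 with DESeq2, 0.059 with limma voom, 0.007 with sex left out, 0.005 with only the compared genotypes, 0.041 with the animal number, 0.064 without the low-marker libraries, 0.062 without both kinds, 0.157 in males and 0.072 in males without the doubted libraries (adjusted p from 0.345 to 1 over its alternatives). In the direct comparison App lost its call in males (-0.493), in females (-0.61) and with the animal number (-0.481), with adjusted p from 2.9e-15 to 0.732 over its alternatives.

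The interferon list kept its direction against WT in each alternative run. Its call for Dp1Tyb was lost in males (0.253), in females (0.275), with the median over members (0.237), with an estimated correlation (0.264) and in males (0.282) and females (0.351) without the doubted libraries, with adjusted p from 0.00113 to 0.218 over its alternatives. For Dp1Tyb;AppKO it was lost in males (0.165), in females (0.469), with an estimated correlation (0.317) and in males without the doubted libraries (0.152), with adjusted p from 0.00027 to 0.366. Without both kinds of library the inhibitory list passed for Dp1Tyb against WT (0.12). The direct difference of the interferon list turned negative in males (-0.087) and in males without the doubted libraries (-0.13), with adjusted p from 0.201 to 0.999.

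Leaving out each of the 46 libraries in turn gave 293 to 565, 439 to 641 and 1 to 1 genes in the 3 comparisons. App then ran from 0.515 to 0.589, from -0.051 to 0.05 and from -0.585 to -0.486, the segment genes from 67 to 73, from 69 to 73 and from 0 to 0, and the interferon list from 0.245 to 0.288, from 0.298 to 0.342 and from 0.034 to 0.072. The ribosomal list ran from -0.138 to -0.118 for Dp1Tyb against WT and kept its call in each case. In the direct comparison it ran from 0.079 to 0.164 and lost its call without any of 12 libraries (Dp1Tyb replicates 2, 3, 4, 8, 9, 10, 11 and 12, Dp1Tyb;AppKO replicates 3, 9, 11 and 13). Oxidative phosphorylation ran from 0.049 to 0.093 there and lost its call without any of 15 (Dp1Tyb replicates 2, 3, 4, 8, 9, 10, 11, 12, 13 and 15, Dp1Tyb;AppKO replicates 1, 3, 11, 12 and 13). For Dp1Tyb against WT it ran from -0.054 to -0.042 and lost its call without any of 24 (WT replicates 1, 3, 4, 6, 7, 8, 10, 11 and 15, Dp1Tyb replicates 1, 2, 3, 4, 8, 9, 10, 11, 12, 13 and 15, Dp1Tyb;AppKO replicates 3, 9, 11 and 13). Sex-dependent genes numbered 0 in each alternative run. No paired analysis was run, because replicate numbers follow the order of deposition and pair no animals. Animals of nearby animal number were not treated as blocks, and that number served only as a covariate. Depth limits the genes near 1 CPM. Changes of the smallest simulated fold were recovered in 58.0% to 64.0% of simulated genes, which were drawn independently.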

Other observations

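Tests chosen only after the result was seen were those of a mixture, of an exchange for Dp1Tyb replicate 16, of the reads of genes overlapping agouti, of an agouti minigene, of the microglia share and of the third App copy as the whole cause, and so were the fits without libraries or with a marker list as covariate. The genes of the following 2 paragraphs were also chosen after their values were seen.

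C4b, Lyz2, Il33 and Serpinb9, which belong to none of the lists, rose in both genotypes with the duplication. C4b, a complement component, rose by 0.50 in Dp1Tyb (adjusted p = 0.000872) and by 0.63 in Dp1Tyb;AppKO (adjusted p = 2.84e-05), and differed by 0.12 between them (adjusted p = 0.659). Lyz2, a lysozyme of myeloid cells, rose by 0.50 (adjusted p = 0.0067) and 0.62 (adjusted p = 0.000518), Il33, an alarmin of glia, by 0.36 (adjusted p = 0.00506) and 0.46 (adjusted p = 0.000306), and Serpinb9, a granzyme inhibitor, by 0.28 (adjusted p = 0.000578) and 0.29 (adjusted p = 0.000313). Sox11 and Sox4, transcription factors of immature neurons, fell by 0.46 (adjusted p = 0.000453) and 0.27 (adjusted p = 0.00614) in Dp1Tyb and by 0.47 (adjusted p = 0.000489) and 0.33 (adjusted p = 0.00067) in Dp1Tyb;AppKO. Wnt7a, a secreted signalling protein, fell by 0.50 in both (adjusted p = 0.000726 and 0.000886).

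The library labelled WT replicate 7 held Car8 at 313 CPM against 2.55 to 9.65 CPM in the other 45 libraries and Fat2 at 142 CPM against 0.129 to 2.55 CPM; both genes are known for their expression in the cerebellum. Calb1, Pvalb and Zic1 also stood highest there, at 316, 111 and 132 CPM. Car8 was called at -2.21 in Dp1Tyb and -2.24 in Dp1Tyb;AppKO against WT (adjusted p = 0.0237 and 0.0218), and without that library the values were -0.24 and -0.24 (adjusted p = 0.469 and 0.505). Fat2 was called at -2.85 and -3.68 (adjusted p = 0.0279 and 0.00665), and without that library it stood at 0.18 and -0.59 (adjusted p = 0.836 and 0.438). The 4 libraries low in hippocampal markers were WT replicate 7, Dp1Tyb replicate 15, Dp1Tyb;AppKO replicate 11 and Dp1Tyb;AppKO replicate 12. Ttr, a choroid plexus transcript, ran from 10.4 to 4153 CPM over the 46 libraries.

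For the 385 genes of Dp1Tyb against WT, 1 of 100 splits, the real one, gave as many. The highest other split gave 2, which argues against chance for that count. For the 495 genes of Dp1Tyb;AppKO against WT, 2 of 100 splits gave as many, the real one included. The highest other gave 551, so such a count was rare among the splits but chance was not excluded. Both counts hold genes of the duplicated region (71 and 72 higher), so the splits do not test the changes outside it by themselves. For the direct comparison 6 of 100 splits gave at least the real count of 1, so chance was not excluded for that count. Its highest other split gave 1158 genes. In that split the myelinating oligodendrocyte, pyramidal and dentate granule lists differed by -0.26, -0.2 and -0.3. Whether tissue composition gave its 1158 genes was not tested. The splits test chance alone. In the real split of Dp1Tyb;AppKO and WT the myelinating oligodendrocyte list differed by 0.16, and in the split with 551 genes by -0.18.

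In 5 libraries App, the segment level or both went against the label. Segment levels were 0.54 in the library labelled WT replicate 5 and 0.02 in that labelled Dp1Tyb replicate 4. Each lies within the range of a single genotype, which argues against a mixture of WT and Dp1Tyb RNA. A score of 171 genes outside the region (0 at WT, 1 at Dp1Tyb) gave 0.70 and 0.01, as an exchange of these labels would. The 0.70 lies under the 0.79 to 1.20 of the other Dp1Tyb libraries. That range comes from libraries that chose the genes and set the scale. Agouti, left out of the score, had 5 and 0 counts, against at most 2 in other WT and at least 4 in other Dp1Tyb libraries. Both libraries are female, with successive animal numbers. For the libraries labelled Dp1Tyb replicates 1 and 16, App changes of 0.08 and -0.02 were predicted from 20 genes that follow App. The measured changes were -0.58 and -0.61, which argues against composition changes that those genes follow as the cause of low App. The 20 genes were picked and fitted in the same kept libraries, so other changes of cell composition stay open. An exchange of the whole library labelled Dp1Tyb replicate 16, female by label and by sex chromosome genes, is argued against by 0 female libraries labelled Dp1Tyb;AppKO at the App level of 3 copies. An exchange of the libraries labelled Dp1Tyb replicate 1 and Dp1Tyb;AppKO replicate 1 stays open, because edgeR, DESeq2 and limma voom each called 0 genes other than App between these genotypes in the other libraries (1455, 1460 and 1025 at an unadjusted p under 0.05), as does a wrong genotype entry without a partner or across the sexes.

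Transcripts of the agouti gene went with the segment at 3 copies, at 1.21 ± 0.499 CPM in 30 libraries against 0.021 ± 0.049 CPM in 16. A fixed share of the reads of the overlapping genes Raly and Eif2s2 is argued against by their log2 fold changes of 0.047 and -0.029, where that of the agouti gene was 4.42, while the related gene Agrp, with 16 counts in total, was not tested. A chromosome 2 haplotype of another strain stays open: 1 of 30 tested neighbours within 1 Mb was called (Mmp24, log2 -0.23, adjusted p = 0.00383) against 2.05% of other genes (Fisher's exact test, p = 0.464), too few to decide. An agouti minigene from the vectors used in chromosome engineering is a candidate explanation. It cannot be told apart from an effect of the segment's dosage on the agouti gene, which lies on chromosome 2. Both predict the counts of 4 to 29 with the extra segment and 0 to 2 without it, a gap of 2.

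The interferon list was higher than in WT with and without the third App copy, by 0.26 and 0.32. Averaged over the sexes, the homeostatic microglia list (21 of 21 members measured, 0 shared with the interferon list) had upper bounds of 0.023 and 0.136. These argue against a larger share of microglia with unchanged marker levels per cell. Members of that list moved both ways in Dp1Tyb (Selplg and Tmem119 lower, Ctss higher), and a change of microglial state was not tested. The choroid plexus list (13 members, 0 shared) had Ttr at 2100 ± 1550 CPM in WT and 2190 ± 1360 CPM in Dp1Tyb. The mural and fibroblast list (14 members, 0 shared) had Igf2 at 172 ± 79.5 and 200 ± 70.7 CPM. With the choroid plexus list as covariate the interferon list differed by 0.261 and 0.31, and with the mural and fibroblast list by 0.201 and 0.286. These differences argue against a larger share of either as the cause. A single library as the cause is argued against by the highest adjusted p of 0.01 when 1 library is left out, which leaves open that several libraries, such as the Dp1Tyb;AppKO females with 0.469 against 0.165 in males (permutation test of the interaction, adjusted p = 0.296), carry more of it. Over both sexes together, the third App copy as the whole cause is argued against by the lower bound of the direct difference, -0.083 and -0.129 without the doubted libraries, while a contribution smaller than these bounds stays open. The third copies of Ifnar1, Ifnar2, Ifngr2 and Il10rb, shared by both genotypes, may contribute and were not tested, since no genotype here separates them from the rest of the segment.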
